A study of Mus musculus with 8 samples.

How the data were processed

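RNA from the colon of 8 male mdr1a-/- mice, 4 on the control diet and 4 on the diet with 0.2% curcumin, was measured on 8 Agilent 2-colour arrays, 1 array per mouse. The series design text describes 3 diets, of which the one with 0.1% rutin is on no array of this series and was not analysed here, and it gives 4 biological replicates per diet on the arrays. Per the series text, arrays were run on control mice with a high histological injury score and curcumin mice with a low one, so the groups differ by selection as well as by diet. The channel labels put the mdr1a-/- sample in Cy3 and a reference in Cy5. The design text speaks of 1 reference RNA on every array, while the channel labels describe the Cy5 RNA as colon of wild-type Swiss mice fed the same diet; the 2 statements differ. Liver list medians of -3.01 to -2.54 and kidney list medians of -2.95 to -2.34 over the 8 arrays are not what 2 colon samples would give, so the reference was not treated as colon; whether its mixture was the same for both diets was not tested. The replicate structure was taken from the sample titles, and nothing beyond these texts says how the reference was made.

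Per the labels' protocols, total RNA was extracted with Trizol and RNeasy columns, 500 ng was amplified and labelled from an oligo-dT primer with a linear amplification kit, the dye content was 10 to 22 pmol per µg, and the scans used the high gain setting. The deposited values are log2 ratios that the authors normalized with limma, per the submitters' processing notes, which give no version. The labels do not state the direction of the ratio. The table has 44290 features in 8 columns and no column without a sample. Values were missing for 5033 features on the array with the fewest gaps (control 3, 11.4%) and for 10529 on that with the most (curcumin 2, 23.8%), and 3072 features had no value on any array. Array medians lay between -0.0201 and -0.0092. For arrays, only their number limits the precision that is stated here.

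Features were named from the platform annotation, checked against the symbols of the mouse gene reference GRCm38.p6 by gene identifier, with 31906 of 32089 named probes matched and 0 symbols changed. A single symbol was found for 32042 features, several for 47 and none for 12201. Probes of 1 gene were averaged on each array, features without a single symbol stayed on their own, and measurements with values on at least 3 arrays per group were kept, which left 24030 to test (17220 named genes and 6810 unnamed features). No further scaling was applied. For 4709 genes with 2 probes the changes of the 2 probes had a correlation of 0.575, against 0.0042 after shuffling, and the same sign in 65.4%.

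The diets were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, curcumin minus control, no covariate). All adjusted p values for genes come from limma with the Benjamini-Hochberg method over the 24030 measurements, two-sided, with a threshold of 0.05; 4423 measurements had an unadjusted p under 0.05. Counts "adjusted over the list alone" apply the same method to the members of a list. Errors after ± are SD over 4 arrays, and SE is the moderated standard error of the difference. The 29 gene lists and 4 reference tissue lists were written before the data were opened, from 861 genes of which 798 are on the array, 10 under an older symbol. Lists were tested with camera in limma with a preset correlation of 0.01, two-sided, Benjamini-Hochberg over the 29 lists, and again with the correlation estimated from the data; fry was run beside it. Labels were read with jsonlite 2.0.0, and figures drawn with Python 3.11.15, matplotlib 3.10.9 and pandas 2.3.3. Medians of list members were bootstrapped with 10000 draws for 95% intervals, resampling genes and not mice.

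The rule for named genes was set before the data were opened: among genes with 1 symbol, an adjusted p under 0.05 and no overlap between the groups, the 12 largest increases and the 12 largest decreases, up to 4 members of each list (those that passed with the largest change, or where none passed the 4 with the smallest p), and Abcb1a with Abcb1b. Apoa1, Xist, Il18, Lbp, Car3 and Nefl in the results, and the genes of name-based families in the closing section, were chosen after their values were seen. The rule for the direction of the ratio was set beforehand and was met on 4 of 8 arrays where 7 were needed; reading it from liver, kidney and Xist alone was chosen after the data were seen.

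On each array 1 log ratio was shared by 191 to 397 features, where the next most frequent value was shared by 3 to 4. These features were kept, because the reason for the shared value is not stated, and were set to missing in an alternative chosen after the data were seen. Of 1137 changed measurements 24 held the shared value on at least 1 array, and 8 held it, in at least 1 probe, on all arrays of a group: Saa1, Saa2, Selenbp1, Selenbp2, Maoa, Neu1, Klk1b5 and Lyz2. Selenbp1 counts among the colonocyte genes, Maoa among phase I and Lyz2 among macrophage genes in the counts of the results.

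Alternatives written beforehand were the array medians subtracted, scale and quantile normalization, each probe on its own, genes with a single probe, measurements present on all 8 arrays, a filter on low values, array weights, robust variance moderation, log ratios limited to -4 to 4, the replicate number as a block, the slide number range as a block, the comparison within the shared slide range, and leaving out each array in turn. The filter on low values dropped measurements with an absolute mean log ratio under 0.5 and an SD over the 8 arrays below the median SD. That SD includes the difference between the diets, so the filter was not blind to the groups. Added after the data were seen were the shared value set to missing, named genes only, the exact permutation test of list means, and the list of 25 pan-epithelial genes. The 35 splits of the 8 arrays into 4 and 4 were run for every count. With the scalings tried, the median log2 fold change over all measurements stayed between -0.0243 and -0.00534.

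The code was tested on simulated data with 24030 measurements. Planted changes of 1.5-fold, 2-fold, 4-fold and 8-fold, 50 of each, were found in 46%, 82%, 98% and 100% of cases, and 8 of 171 calls were false (4.68%). The 1 list that was shifted was found and 0 others of 29 were called. The simulated noise was independent between genes, whereas the correlation estimated from the data was 0.338 in the macrophage list and 0.639 in the proliferation list. The simulation therefore does not show how often camera with the preset correlation calls lists whose members vary together.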

Results

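Gene expression was measured in the colon of 8 male mdr1a-/- mice, which lack the drug efflux transporter encoded by Abcb1a and develop colitis. There were 4 mice on the AIN-76A control diet and 4 mice on the same diet with 0.2% curcumin, the yellow polyphenol of turmeric. Each mouse had its own 2-colour Agilent array, on which its RNA was labelled with Cy3 and hybridised beside a reference RNA labelled with Cy5. The deposited values are log2 ratios for 44290 features, of which 24030 gene-level measurements, 17220 of them named genes, could be tested. The number of arrays limits the precision: the median standard error of a log2 difference between the diets was 0.11. Per the series description, the control mice on the arrays had a high histological injury score and the curcumin mice a low one, so diet and injury score differ together between the 2 groups. The texts describe the reference as 1 RNA on every array and also as wild-type colon on the same diet as the sample. The measured ratios to the reference, given with the direction of the ratio, do not have the values that colon against colon would give. The labels give an age of 7 weeks, while the design text describes mice followed from 7 to 24 weeks.

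The labels do not say which way the ratio runs. Signs below assume that each value is the mouse sample over the reference. Under the rule set beforehand, colonocyte genes had to lie more than 0.50 above liver, kidney and fetal genes on at least 7 arrays, and this held on 4 of 8 arrays, so the direction was not settled by it. The colonocyte median lay 2.40 to 3.55 above the liver median and 2.06 to 3.30 above the kidney median on all 8 arrays, but -0.14 to 0.81 above the fetal median. On curcumin arrays 1 to 3 the colonocyte median was itself a log ratio that many features shared. The liver-secreted apolipoprotein Apoa1 had log ratios between -4.52 and -3.86. Xist, the transcript of the inactive X chromosome of female cells, had log ratios between -1.57 and -1.05 in these male mice. If the ratio ran the other way, every sign below would turn, with 633 higher and 504 lower. That reading would put more liver, kidney and Xist transcript in the colon of male mice than in the reference, on all 8 arrays. The liver, kidney, Apoa1 and Xist values argue against it, although this check was chosen after the data were seen. Against the reference, the liver list had a median log ratio of -2.73 ± 0.19 (SD, n = 4) in the control group and -2.79 ± 0.19 in the curcumin group, and the kidney list -2.46 ± 0.21 and -2.77 ± 0.12. Single arrays ran from -3.01 to -2.54 for liver and from -2.95 to -2.34 for kidney, so in either direction of the ratio 1 channel held far more liver and kidney transcript on all 8 arrays, which colon as the only source of both channels would not give. The fetal tissue list had medians of -0.13 ± 0.02 and -0.25 ± 0.03, and the list of muscle, heart and brain genes -0.67 ± 0.29 and -0.70 ± 0.05.

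Abcb1a, the disrupted gene, had a log ratio of -0.55 ± 0.10 (SD, n = 4) in control mice and -0.19 ± 0.18 in curcumin mice, with single arrays from -0.67 to 0.05. The difference did not pass (log2 fold change 0.37, SE 0.10, adjusted p = 0.081). Its close copy Abcb1b had log ratios of 0.14 ± 0.04 and -0.16 ± 0.15, and this difference did not pass either (-0.30, SE 0.09, adjusted p = 0.0926). Per the labels both groups carry the disruption, so these values do not check the labels of the diets. They do not show a loss of the transcript either, and where the probe lies relative to the disruption was not examined here.

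The comparison of the diets asked which colon genes differ between colitis-prone mice eating curcumin and those eating the control diet. Among colonocyte genes 11 of 33 rose with curcumin, among phase I xenobiotic genes 15 of 46, and among genes of oxidative phosphorylation and the citric acid cycle 7 of 43, and none of these lists held a gene that fell. Among macrophage and dendritic cell genes 12 of 21 fell, among matrix genes 8 of 23, among neutrophil genes 4 of 16 and among T cell genes 4 of 22, and none rose. With an estimated correlation the colonocyte list and the list of oxidative phosphorylation passed upward as a whole, and no list passed downward. In limma, 1137 genes and unnamed features changed between the diets, 504 higher and 633 lower with curcumin, and 747 of them changed by at least 1.5-fold. Among named genes 958 changed, 429 higher and 529 lower, and in 952 of these the 4 control values and the 4 curcumin values did not overlap. Passing the threshold with 4 against 4 arrays nearly requires this, so it adds no support of its own. Over all measurements tested 12.6% did not overlap, where chance gives 2.86%. At least 2-fold changes were seen in 109 higher and 155 lower named genes. After quantile normalization the split between directions turned to 619 higher and 489 lower. The first principal component held 40.5% of the variance and separated the diets. Correlations between arrays ran from 0.772 to 0.907 within the control group, from 0.862 to 0.908 within the curcumin group and from 0.727 to 0.825 between the groups.

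The largest increase was in Hao2, a peroxisomal hydroxyacid oxidase, from -2.49 ± 0.71 (SD, n = 4) in control mice to 1.25 ± 0.60 (SD, n = 4) with curcumin, a 13.4-fold change (log2 fold change 3.74, SE 0.38, adjusted p = 0.00182). Gsdmc2, a member of the gasdermin family, rose by a log2 fold change of 2.61 (SE 0.30, adjusted p = 0.00278). Scin, which encodes an actin-severing protein, rose from -1.44 ± 0.54 to 1.02 ± 0.21 (2.45, SE 0.24, adjusted p = 0.0018). Acer1, an alkaline ceramidase, rose from 0.49 ± 0.36 to 2.75 ± 0.12 (2.26, SE 0.17, adjusted p = 0.000595). The chloride-bicarbonate exchanger Slc26a3 rose from -0.35 ± 0.29 to 1.82 ± 0.41 (2.17, SE 0.21, adjusted p = 0.00175); its 3 probes gave 0.20, 2.35 and 3.26. The membrane-bound carbonic anhydrase Car4 rose from -0.49 ± 0.54 to 1.92 ± 0.70 (2.41, SE 0.36, adjusted p = 0.00806). The dicarboxylate transporter Slc13a2 rose from -0.96 ± 0.44 to 1.27 ± 0.25 (2.23, SE 0.22, adjusted p = 0.00175). Kcne3, a regulatory subunit of potassium channels, rose from 0.17 ± 0.36 to 2.35 ± 0.38 (2.18, SE 0.22, adjusted p = 0.0018). The peptide transporter Slc15a1 rose from -1.38 ± 0.45 to 0.72 ± 0.42 (2.10, SE 0.25, adjusted p = 0.00355). The remaining 3 of the 12 largest increases were in enzymes that act on drugs and other foreign compounds. They were the cytochrome P450 Cyp2c40 (2.17, SE 0.23, adjusted p = 0.00203) and the sulfotransferases Sult1a1 (2.16, SE 0.21, adjusted p = 0.00175) and Sult1c2 (2.16, SE 0.32, adjusted p = 0.00787).

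The largest decrease was in S100a8, from 2.88 ± 0.76 (SD, n = 4) to -0.19 ± 0.90 (log2 fold change -3.07, SE 0.48, adjusted p = 0.00944). Its partner in the calprotectin complex of neutrophils and monocytes, S100a9, fell from 2.58 ± 0.60 to 0.02 ± 1.27 (-2.56, SE 0.57, adjusted p = 0.037). The myeloid C-type lectin Clec4d fell from 3.15 ± 1.07 to 0.31 ± 0.42 (-2.84, SE 0.47, adjusted p = 0.0119). Cstdc6 and Stfa3, which encode cystatin-type protease inhibitors, fell by log2 fold changes of -2.83 (SE 0.61, adjusted p = 0.0338) and -2.31 (SE 0.54, adjusted p = 0.0457). The inflammatory cytokine gene Il1b fell from 3.17 ± 0.67 to 0.86 ± 0.76 (-2.31, SE 0.42, adjusted p = 0.0171). Ido1, a tryptophan-degrading enzyme induced by interferon, fell from 2.53 ± 0.36 to 0.29 ± 1.21 (-2.24, SE 0.51, adjusted p = 0.0419). The interferon-induced chemokine Cxcl11 fell from 2.52 ± 0.74 to 0.29 ± 0.87 (-2.23, SE 0.47, adjusted p = 0.0297). Among protease genes, Mmp7 fell from 1.18 ± 0.92 to -1.32 ± 0.20 (-2.50, SE 0.38, adjusted p = 0.0088) and Adam8 from 1.90 ± 0.57 to -0.32 ± 0.21 (-2.22, SE 0.25, adjusted p = 0.00275). Ccdc88b fell from 2.79 ± 0.36 to 0.59 ± 0.55 (-2.20, SE 0.27, adjusted p = 0.00391). Wfdc21, of the whey acidic protein family, fell from -1.40 ± 1.12 to -3.75 ± 0.19 (-2.35, SE 0.46, adjusted p = 0.024).

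**Figure D1:**
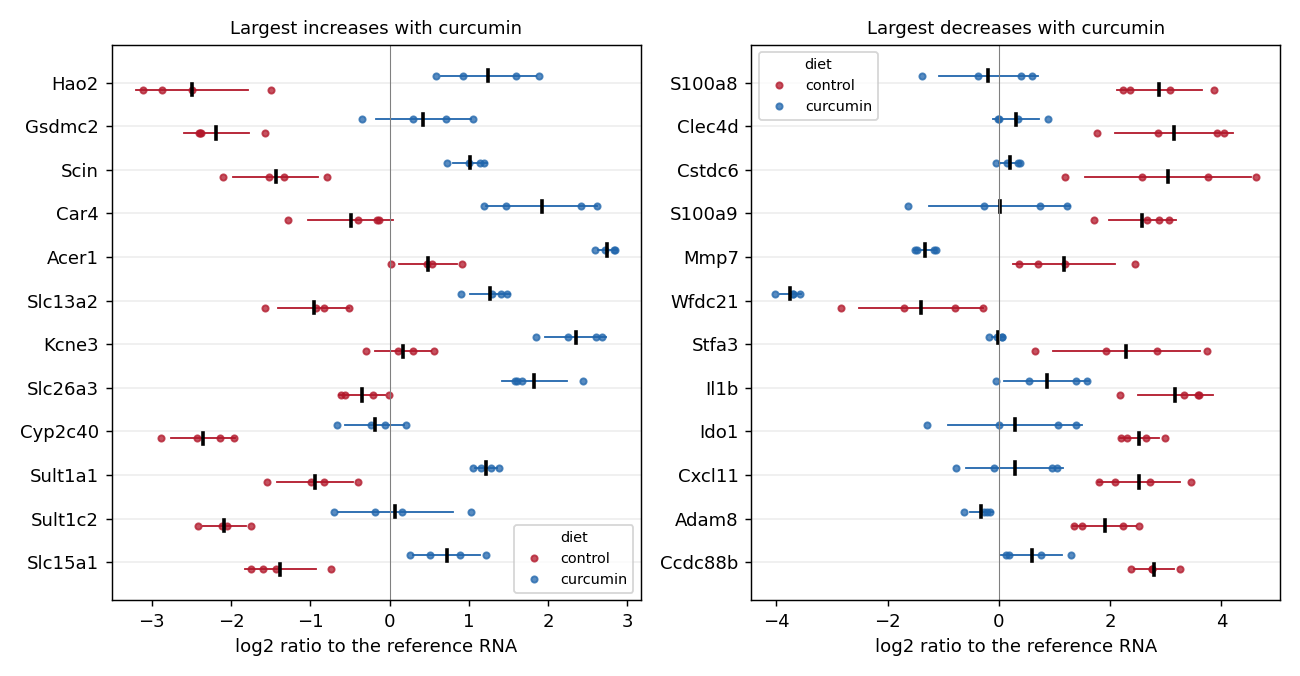
Log2 ratio of sample to reference in each of the 4 control (red) and 4 curcumin (blue) arrays for the 12 named genes with the largest increase and the 12 with the largest decrease, with the group mean as a black tick and a line of 1 SD to each side. In each gene the 4 curcumin values lie on 1 side of the 4 control values, which the rule for choosing these genes required. For Hao2 the means are -2.49 and 1.25, for S100a8 2.88 and -0.19.

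Of these 24 genes, all 12 increases stayed past the threshold whichever array was left out, as did the decreases of S100a8, Clec4d, Mmp7, Adam8 and Ccdc88b, while the other 7 decreases lost the call in at least 1 such fit. The 4 control arrays and curcumin arrays 1 and 2 came from 1 range of slide numbers and curcumin arrays 3 and 4 from another. With the range as a block 330 genes and features changed, with 9 of the 12 largest decreases lost, and within the shared range 175 changed, with all 12 decreases and Car4 lost. The decreases were as large within the shared range, 0.932 to 1.18 times the full change (S100a8 -3.37, SE 0.61), while their median SE went from 0.466 to 0.605 with 2 curcumin arrays fewer. The increases ranged from 0.754 to 1.32 times the full change there. The lowest was that of Car4, which went from 2.41 to 1.82.

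Among the innate immune genes below, all that passed fell with curcumin apart from Il18. Of 16 neutrophil genes tested, 4 fell and none rose (0 higher and 11 lower, adjusted over the list alone). They were S100a8, S100a9, Stfa3 and the lactoferrin gene Ltf (-1.13, SE 0.24, adjusted p = 0.0307). The list shifted down (median log2 fold change -0.69, -0.83 within the shared slide range, adjusted p = 3.88e-07 in camera; adjusted p = 0.145 with an estimated correlation). Of 21 macrophage and dendritic cell genes, 12 fell and none rose (0 and 18 adjusted over the list alone). The fungal-glucan receptor Clec7a fell by -1.80 (SE 0.37, adjusted p = 0.0282), the signalling adaptor Tyrobp from 2.62 ± 0.29 (SD, n = 4) to 1.06 ± 0.39 (-1.56, SE 0.20, adjusted p = 0.00484). The Fc receptor gene Fcgr3 fell by -1.41 (SE 0.27, adjusted p = 0.0207) and the complement gene C1qc from 1.80 ± 0.10 to 0.54 ± 0.29 (-1.25, SE 0.14, adjusted p = 0.00235). This list had a median of -0.96, and -0.94 within the shared slide range (adjusted p = 1.05e-13 in camera; adjusted p = 0.0683 with an estimated correlation). Among 28 proinflammatory cytokine and chemokine genes, 7 fell and 1 rose (1 higher and 10 lower, adjusted over the list alone). Beside Il1b and Cxcl11, the interferon-induced chemokine Cxcl9 fell (-2.02, SE 0.42, adjusted p = 0.0282), as did the neutrophil-attracting chemokine Cxcl1 (-1.69, SE 0.39, adjusted p = 0.0443). The 1 that rose was Il18, a cytokine also made by epithelium, from -0.10 ± 0.21 to 1.20 ± 0.25 (1.30, SE 0.15, adjusted p = 0.00264). The list median was -1.03, and -1.09 within the shared slide range (adjusted p = 6.56e-07 in camera; adjusted p = 0.31 with an estimated correlation). Of 27 genes of the interferon-gamma response and antigen presentation, 6 fell and none rose (0 and 16 adjusted over the list alone). Among them were Ido1 and the interferon-induced GTPases Gbp3 (-2.08, SE 0.29, adjusted p = 0.00681), Iigp1 (-1.91, SE 0.44, adjusted p = 0.0425) and Gbp4 (-1.84, SE 0.40, adjusted p = 0.0342). Their median was -0.60, and -1.02 within the shared slide range (adjusted p = 5.83e-09 in camera; adjusted p = 0.217 with an estimated correlation).

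Of 22 T cell genes, 4 fell and none rose (0 and 13 adjusted over the list alone). These were the receptor subunit Cd3d (-0.82, SE 0.16, adjusted p = 0.024), the adaptor Lat (-0.77, SE 0.17, adjusted p = 0.037), Cd6 (-0.61, SE 0.13, adjusted p = 0.0322) and the costimulatory receptor Icos (-0.41, SE 0.08, adjusted p = 0.0242). The 2 probes of Cd6 differed, at -0.05 and -1.16, as did those of Icos, at -0.14 and -0.69. The T cell list had a median of -0.30, and -0.32 within the shared slide range (adjusted p = 2.03e-07 in camera; adjusted p = 0.146 with an estimated correlation). Of 20 B cell and plasma cell genes none passed, also when adjusted over the list alone, and the list did not pass (median -0.16, -0.19 within the shared slide range, adjusted p = 0.128 in camera). It passed downward without control array 3 (adjusted p = 0.00062), without curcumin array 3 (adjusted p = 0.0312) and with array weights (adjusted p = 0.0372). Here Pou2af1 had -1.18 (SE 0.36, adjusted p = 0.11), Ighm -0.66 (SE 0.22, adjusted p = 0.144), Igha -0.48 (SE 0.22, adjusted p = 0.293) and Ltb -0.48 (SE 0.25, adjusted p = 0.362). Of 16 mast cell and eosinophil genes none passed (1 higher and 1 lower, adjusted over the list alone), and the list did not pass (adjusted p = 0.483), with a median of 0.02 and a mean of -0.05. In that list Kit had 0.40 (SE 0.10, adjusted p = 0.0659), Hdc -1.51 (SE 0.42, adjusted p = 0.082), Siglecf 0.20 (SE 0.10, adjusted p = 0.364) and Epx -0.22 (SE 0.12, adjusted p = 0.408). The antimicrobial genes of the epithelium held 24 tested members, of which 3 fell. They were the secreted phospholipase Pla2g2a (-1.84, SE 0.40, adjusted p = 0.0352), Ltf and the lipopolysaccharide-binding protein gene Lbp (-0.74, SE 0.15, adjusted p = 0.0284). The 2 that passed upward were Saa1 (-0.60 ± 0.26 in control and 0.40 ± 0.09 with curcumin, adjusted p = 0.00399) and Saa2 (-0.74 ± 0.60 and 0.40 ± 0.09, adjusted p = 0.0373). On all 4 curcumin arrays Saa2 and at least 1 of the 2 probes of Saa1 sat at 1 log ratio that 191 to 397 features share on each array. Both stay in the counts, but their values are not read as rises of these genes. Adjusted over the list alone 4 were higher and 5 lower, and the list as a whole did not pass (median -0.20, adjusted p = 0.703).

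Of 23 matrix remodelling genes, 8 fell and none rose (0 and 18 adjusted over the list alone). Beside Mmp7, the collagenase gene Mmp13 fell from 1.37 ± 0.34 (SD, n = 4) to 0.04 ± 0.22 (-1.33, SE 0.18, adjusted p = 0.00497), the fibrillar collagen gene Col1a2 by -1.28 (SE 0.22, adjusted p = 0.0137) and the matrix glycoprotein gene Sparc by -1.04 (SE 0.22, adjusted p = 0.0314). The list had a median of -0.67, also -0.67 within the shared slide range (adjusted p = 8.77e-12 in camera; adjusted p = 0.0675 with an estimated correlation). Of 28 stem cell and proliferation genes, 2 fell and none rose (0 and 7 adjusted over the list alone), the mitotic kinase Aurkb (-1.01, SE 0.24, adjusted p = 0.0475) and the ribonucleotide reductase subunit Rrm2 (-0.75, SE 0.13, adjusted p = 0.0171). Their median was -0.39, and -0.42 within the shared slide range (adjusted p = 3.2e-06 in camera; adjusted p = 0.346 with an estimated correlation). Of 20 endothelial genes, 3 fell and none rose (0 and 4 adjusted over the list alone): Egfl7 (-0.59, SE 0.13, adjusted p = 0.0384), Eng (-0.41, SE 0.09, adjusted p = 0.0334) and Esam (-0.30, SE 0.07, adjusted p = 0.0493). The endothelial median was -0.23, and -0.20 within the shared slide range (adjusted p = 0.000562 in camera; adjusted p = 0.31 with an estimated correlation).

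All colonocyte, goblet cell and enteroendocrine genes that passed rose with curcumin. Of 33 colonocyte genes, 11 rose and none fell (16 and 0 adjusted over the list alone). Beside Car4, Slc26a3 and Sult1a1, the water channel gene Aqp4 rose from 0.64 ± 0.51 (SD, n = 4) to 2.13 ± 0.33 (1.48, SE 0.25, adjusted p = 0.0133). The list had a median of 0.73, and 0.61 within the shared slide range, and its shift held with an estimated correlation (adjusted p = 1.51e-13 in camera, adjusted p = 0.0165 with an estimated correlation). Of 25 genes expressed across all epithelial cells, a list chosen after the data were seen, Ehf, Cldn3, Cgn, Esrp2 and Grhl2 rose and none fell. The 20 of them that held the shared log ratio on no array had a median of 0.35. Of 19 goblet cell genes, 3 rose and none fell (4 and 0 adjusted over the list alone). They were the kallikrein Klk1 (1.28, SE 0.23, adjusted p = 0.0171), the calpain Capn9 (0.89, SE 0.17, adjusted p = 0.0208) and the tryptase-like protease Tpsg1, from 0.29 ± 0.08 to 1.17 ± 0.17 (0.88, SE 0.10, adjusted p = 0.00231). The goblet cell median was 0.38, and 0.14 within the shared slide range (adjusted p = 0.000437 in camera; adjusted p = 0.217 with an estimated correlation). Of 17 enteroendocrine genes, 4 rose and none fell (6 and 0 adjusted over the list alone). The hormone gene Insl5 rose from 0.27 ± 0.22 to 1.63 ± 0.36 (1.36, SE 0.18, adjusted p = 0.00538). The others were the granule protein genes Chga (1.34, SE 0.16, adjusted p = 0.00363) and Chgb (0.95, SE 0.22, adjusted p = 0.0458), and somatostatin, Sst (0.54, SE 0.10, adjusted p = 0.0221). This list had a median of 0.22, and 0.37 within the shared slide range (adjusted p = 4.95e-07 in camera; adjusted p = 0.0675 with an estimated correlation).

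**Figure D2:**
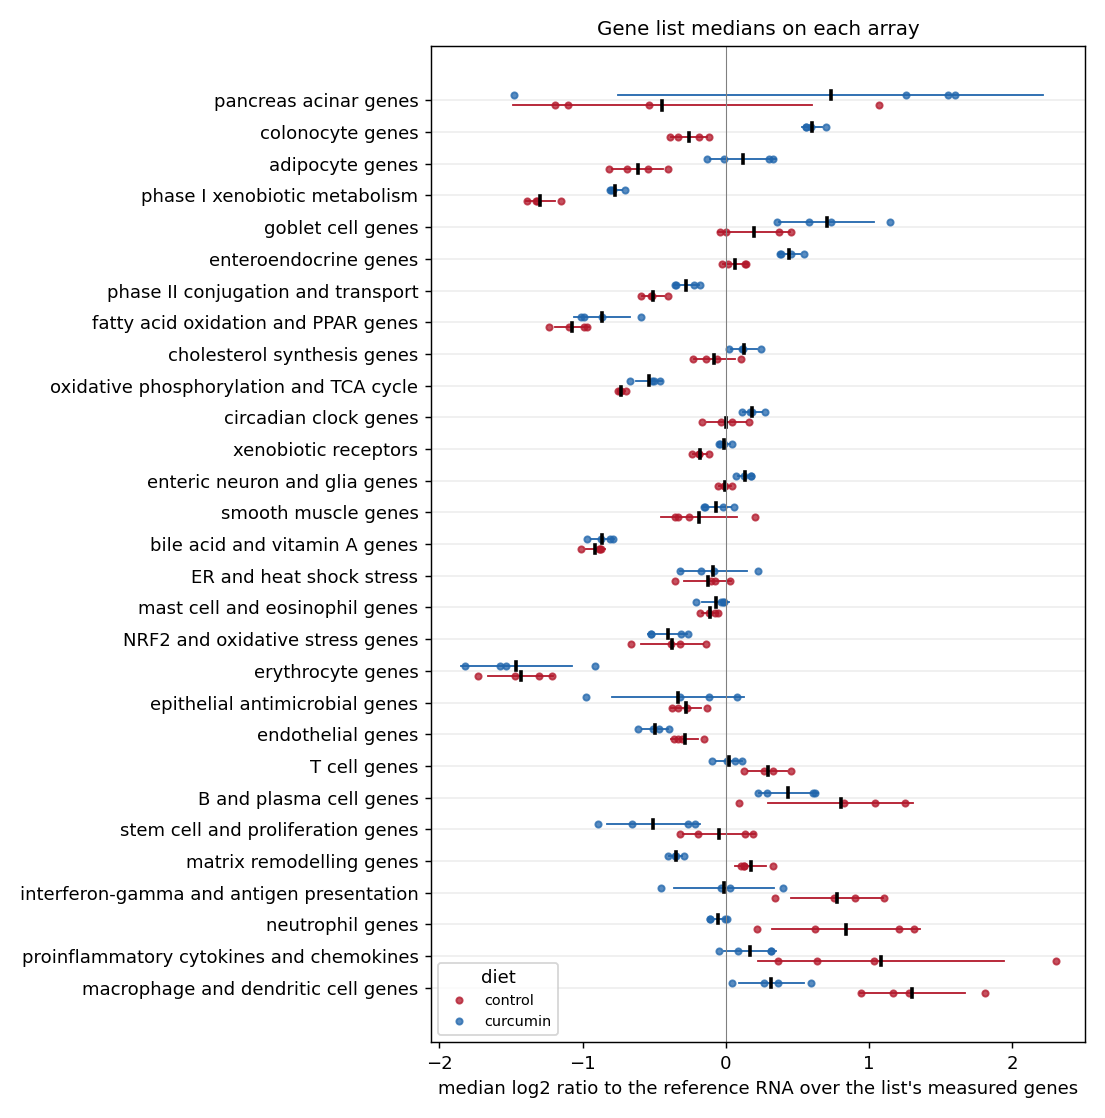
Median log2 ratio of sample to reference over the genes of each of 29 lists in each of the 4 control (red) and 4 curcumin (blue) arrays, sorted by the difference between the groups, with the group mean as a black tick and a line of 1 SD to each side; features at the shared log ratio are left out. The colonocyte list runs from a mean of -0.26 in control to 0.60 with curcumin, and the macrophage and dendritic cell list from 1.30 to 0.32.

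Of the genes in the 3 fixed lists of phase I, phase II and xenobiotic receptors that passed, all but Slco3a1 rose with curcumin. Of 46 phase I genes, 15 rose and none fell (22 and 2 adjusted over the list alone). Beside Cyp2c40, the cytochromes P450 Cyp2c55 (1.82, SE 0.40, adjusted p = 0.0363) and Cyp3a13 (1.78, SE 0.19, adjusted p = 0.00229) rose, as did the monoamine oxidase Maob, from -1.76 ± 0.28 (SD, n = 4) to -0.14 ± 0.27 (1.62, SE 0.17, adjusted p = 0.00189). The list median was 0.41, and 0.36 within the shared slide range (adjusted p = 5.83e-09 in camera; adjusted p = 0.0683 with an estimated correlation). Of 46 genes of phase II conjugation and transport, 12 rose and 1 fell (16 and 2 adjusted over the list alone). The efflux transporter Abcg2 rose from -2.10 ± 0.15 to -0.54 ± 0.19 (1.56, SE 0.12, adjusted p = 0.000607), beside Sult1a1 and Sult1c2, while the organic anion transporter Slco3a1 fell from -0.40 ± 0.24 to -1.95 ± 0.37 (-1.54, SE 0.19, adjusted p = 0.00353). Here the median was 0.29, and 0.25 within the shared slide range (adjusted p = 2.25e-08 in camera; adjusted p = 0.0675 with an estimated correlation). Of 20 xenobiotic receptors and their partners, 4 rose and none fell (8 and 0 adjusted over the list alone). They were the vitamin D receptor Vdr (0.82, SE 0.11, adjusted p = 0.00641), the fatty acid receptor Ppara (0.80, SE 0.13, adjusted p = 0.0108), the coactivator Ppargc1b (0.52, SE 0.09, adjusted p = 0.0164) and Nr1i2, which encodes the pregnane X receptor (0.47, SE 0.11, adjusted p = 0.045). The receptor list had a median of 0.14, and 0.16 within the shared slide range (adjusted p = 0.000197 in camera; adjusted p = 0.0546 with an estimated correlation). Of 28 NRF2 and oxidative stress genes, 1 rose, the catalase gene Cat (0.60, SE 0.13, adjusted p = 0.0292), and none fell (1 and 1 adjusted over the list alone). This list did not pass (adjusted p = 0.877), with a median of 0.04 and a mean of -0.03.

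Of 43 genes of oxidative phosphorylation and the citric acid cycle, 7 rose and none fell (10 and 0 adjusted over the list alone). The complex III subunit Uqcrc2 rose from -0.52 ± 0.07 (SD, n = 4) to 0.13 ± 0.18 (0.65, SE 0.10, adjusted p = 0.00854), with the succinyl-CoA ligase subunit Suclg1 (0.63, SE 0.12, adjusted p = 0.0201), the complex I subunit Ndufs1 (0.47, SE 0.10, adjusted p = 0.0299) and the succinate dehydrogenase subunit Sdha (0.42, SE 0.08, adjusted p = 0.0171). The 3 probes of Sdha gave 0.15, 0.46 and 0.64. The list median was 0.26, and 0.22 within the shared slide range, and this shift held with an estimated correlation (adjusted p = 2.56e-09 in camera, adjusted p = 0.0165 with an estimated correlation). The 20 pan-epithelial genes above had a median of 0.35, and whether a larger share of epithelium gives the shift of this list was not tested. Of 36 genes of fatty acid oxidation and PPAR targets, 6 rose and 1 fell (13 and 1 adjusted over the list alone). The oxidation enzymes Ech1 (1.07, SE 0.11, adjusted p = 0.00189), Acaa2 (1.06, SE 0.12, adjusted p = 0.00272) and Hadh (0.75, SE 0.12, adjusted p = 0.00937) rose, and Angptl4, an inhibitor of lipoprotein lipase, fell (-0.90, SE 0.21, adjusted p = 0.0465). The list median was 0.21, and 0.17 within the shared slide range (adjusted p = 6.49e-06 in camera; adjusted p = 0.133 with an estimated correlation). Of 20 cholesterol synthesis genes, 2 rose and none fell (3 and 0 adjusted over the list alone): Hmgcs1 (0.54, SE 0.08, adjusted p = 0.00719) and Dhcr7 (0.48, SE 0.08, adjusted p = 0.0111). The 2 probes of Hmgcs1 gave 0.27 and 0.81. The cholesterol list median was 0.19, and 0.15 within the shared slide range (adjusted p = 5.75e-05 in camera; adjusted p = 0.168 with an estimated correlation). Of 19 bile acid and vitamin A genes, 1 rose, the retinol saturase Retsat (0.61, SE 0.10, adjusted p = 0.0103), and none fell, also when adjusted over the list alone. As a whole it did not pass (median -0.08, adjusted p = 0.438).

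Of 15 adipocyte genes, 5 rose and none fell (11 and 0 adjusted over the list alone). The lipid droplet protein gene Cidec rose from -0.65 ± 0.36 (SD, n = 4) to 1.29 ± 0.25 (1.93, SE 0.19, adjusted p = 0.00175) and the adiponectin gene Adipoq from -0.25 ± 0.32 to 1.59 ± 0.58 (1.84, SE 0.28, adjusted p = 0.00814). The fatty acid binding protein Fabp4 (1.13, SE 0.17, adjusted p = 0.00848), the gluconeogenic enzyme Pck1 (1.11, SE 0.24, adjusted p = 0.0328) and the carbonic anhydrase Car3 (0.96, SE 0.21, adjusted p = 0.0334) rose too. The call of Fabp4 was lost with the shared log ratio set to missing (adjusted p = 0.0747). The list median was 0.73, and 1.03 within the shared slide range (adjusted p = 6.24e-11 in camera; adjusted p = 0.0675 with an estimated correlation). Of 15 pancreas acinar genes, the elastase Cela1 rose (1.77, SE 0.39, adjusted p = 0.0352), 1 gene also when adjusted over the list alone. The acinar medians per array were 1.07, -1.19, -1.10 and -0.54 in control mice and 1.55, 1.26, -1.48 and 1.60 in curcumin mice (median difference 1.19, 1.93 within the shared slide range, adjusted p = 8.34e-05 in camera; adjusted p = 0.317 with an estimated correlation). None of 5 erythrocyte genes passed with either adjustment, and the list did not pass (adjusted p = 0.885, median -0.07, mean 0.06). Among its members Ank1 had -0.27 (SE 0.10, adjusted p = 0.193), Hemgn 0.27 (SE 0.13, adjusted p = 0.341), Hba-a1 0.51 (SE 0.41, adjusted p = 0.584) and Slc4a1 -0.07 (SE 0.07, adjusted p = 0.67).

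Of 20 enteric neuron and glia genes, 4 rose and 1 fell (5 and 1 adjusted over the list alone). The synaptic gene Snap25 (0.76, SE 0.16, adjusted p = 0.0289), the ubiquitin hydrolase Uchl1 (0.58, SE 0.13, adjusted p = 0.0395), the neuronal RNA-binding protein Elavl4 (0.49, SE 0.10, adjusted p = 0.0295) and the neurofilament gene Nefl (0.45, SE 0.09, adjusted p = 0.0254) rose, while the membrane glycoprotein gene Gpm6b fell from 1.74 ± 0.24 (SD, n = 4) to 0.32 ± 0.29 (-1.42, SE 0.16, adjusted p = 0.00278). The list median was 0.10, and 0.09 within the shared slide range (adjusted p = 0.00305 in camera; adjusted p = 0.19 with an estimated correlation). None of 20 smooth muscle genes passed with either adjustment. Lmod1 had 0.30 (SE 0.15, adjusted p = 0.349), Myh11 0.52 (SE 0.27, adjusted p = 0.358), Myl9 0.32 (SE 0.17, adjusted p = 0.36) and Mylk 0.25 (SE 0.15, adjusted p = 0.427). On all 4 curcumin arrays and 1 control array Myl9 sat at the log ratio that many features share, so its difference is not read as a change of this gene. The smooth muscle list median was 0.15, also 0.15 within the shared slide range (adjusted p = 0.00687 in camera; adjusted p = 0.45 with an estimated correlation). Without control array 1 the adjusted p was 0.0577. Of 17 circadian clock genes, Per2 rose (0.58, SE 0.13, adjusted p = 0.0354) and the repressor Nfil3 fell (-1.20, SE 0.23, adjusted p = 0.0221), with 2 higher and 1 lower when adjusted over the list alone. The 2 probes of Per2 gave 0.04 and 1.13. The clock list median was 0.15, and 0.09 within the shared slide range (adjusted p = 0.0121 in camera; adjusted p = 0.31 with an estimated correlation), and its call was lost within that range (adjusted p = 0.0619). None of 25 genes of the endoplasmic reticulum and heat shock stress responses passed with either adjustment. Ddit3 had 0.82 (SE 0.26, adjusted p = 0.112), Dnajb9 0.39 (SE 0.20, adjusted p = 0.358), Atf3 0.97 (SE 0.52, adjusted p = 0.376) and Canx 0.19 (SE 0.10, adjusted p = 0.388). That list had a median of 0.11, and 0.16 within the shared slide range (adjusted p = 0.0391 in camera; adjusted p = 0.523 with an estimated correlation). Its call was also lost without control array 2 (adjusted p = 0.178), control array 3 (0.294), curcumin array 1 (0.584) or curcumin array 4 (0.0571).

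**Figure D3:**
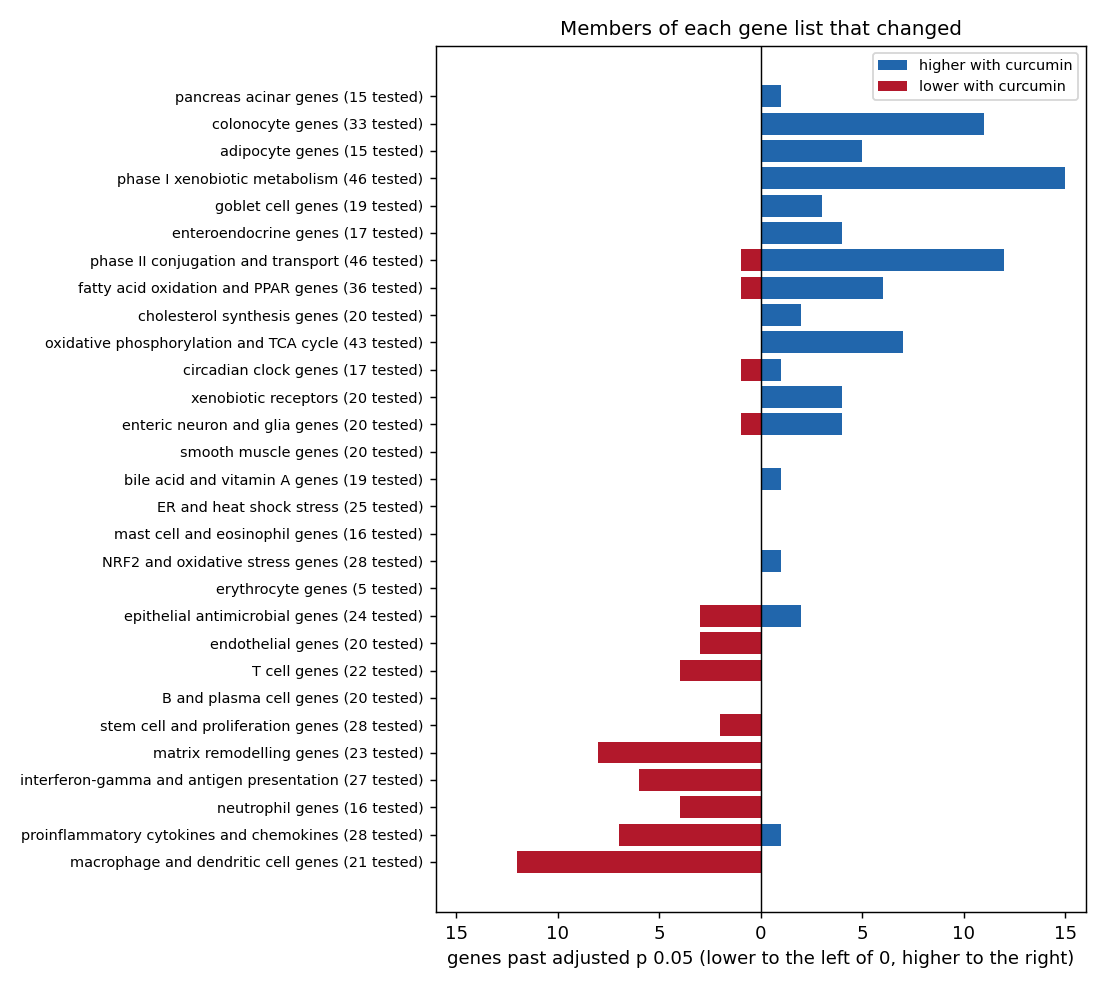
Number of genes in each of 29 lists that passed an adjusted p of 0.05, with genes higher with curcumin as bars to the right and genes lower with curcumin as bars to the left. The longest bar to the right is that of phase I xenobiotic metabolism, with 15 higher, and the longest to the left that of macrophage and dendritic cell genes, with 12 lower.

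In camera with the preset correlation, 15 of 29 lists shifted up with curcumin and 8 down. This setting also called lists in splits of the arrays that put 2 control and 2 curcumin arrays on each side. With control 1, control 4, curcumin 2 and curcumin 3 on 1 side it called 3 lists up and 7 down, with 0 genes changed. With control 1, control 3, curcumin 3 and curcumin 4 on 1 side it called 0. Its p values may therefore be too small in these data. With the correlation estimated from the data, 2 lists passed upward, the colonocyte list and the list of oxidative phosphorylation and the citric acid cycle, and none passed downward. In fry 9 lists passed upward and 5 downward, and 9 of the lists that passed in camera did not pass there. Those 9 were the cytokine (adjusted p = 0.0941), proliferation (0.111), endothelial (0.0732), goblet cell (0.06), clock (0.193), acinar (0.234), neuron and glia (0.0591), smooth muscle (0.394) and stress response (0.518) lists. In an exact permutation test of the mean of each list over all 70 arrangements of the arrays, chosen after the data were seen, 15 lists reached the smallest possible p of 0.0286, and none passed after adjustment. The adjusted p of those 15 lists was 0.0552 in this test. With 8 arrays a list could pass only if more of the 29 lists had reached that smallest p. The lack of a pass therefore does not speak against the shift of any single list.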

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

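The named genes and the list medians gave 288 groups of 4 arrays, of which those of Epx and Hemgn, with only 3 values each, were not scanned. Of the others, 17 held 1 array far from the other 3 by Dixon's test at 95%, and chance flags about 5 percent of groups. This rule was set before the data were examined, and the test of the shared value below was written after that value was noticed but before its own result was seen. Among genes, Gsdmc2 stood at -1.57 on control array 2 against -2.40 to -2.38 on the other control arrays, and Ech1 at -0.58 on control array 1 against -0.996 to -0.929. Suclg1 was at -1.60 on control array 2 against -1.19 to -1.12, and Myh11 at 1.47 on control array 3 against 0.23 to 0.40. Elavl4 was at 0.21 on control array 3 against 0.25 to 0.26. Slc26a3 was at 2.44 on curcumin array 2 against 1.58 to 1.67, Cd6 at -0.16 on curcumin array 1 against 0.16 to 0.21, and Maob at -0.54 on curcumin array 3 against -0.04 to 0.04.

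Among list medians, mast cell and eosinophil genes stood at -0.21 on curcumin array 3 against -0.04 to -0.01, and pancreas acinar genes at -1.48 on the same array against 1.26 to 1.60. Matrix remodelling genes were at 0.33 on control array 3 against 0.10 to 0.13, and bile acid and vitamin A genes at -1.01 on control array 1 against -0.88 to -0.87. Kidney genes were at -2.77 on control array 4 against -2.36 to -2.34, and fetal tissue genes at -0.095 on the same array against -0.14 to -0.13. The reasons were not tested.

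Saa1, Saa2 and Myl9 each stood at 0.53 on curcumin array 2, against 0.34 to 0.36 on the other curcumin arrays. For Saa2 and Myl9 these are the value that 191 to 397 features share on each array, while Saa1, the mean of 2 probes, had 0.347 on curcumin array 1 and the shared value on the others. The shared values were 0.33, 1.01, 0.51 and 0.38 on control arrays 1 to 4, and 0.34, 0.53, 0.35 and 0.36 on curcumin arrays 1 to 4. The sets of features at the shared value overlapped between arrays by a median of 89.8% of the smaller set (78.2% to 97.2%), where 0.844% would be met by chance, which is what saturation of both channels at the top of the scanner range may give; the signals themselves were not used here. The spread of Saa2 and Myl9 among the curcumin arrays is that of the shared value.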

How the results depend on the processing

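The shared value set to missing, named genes only and the reading of the direction from liver and kidney were chosen after the data were seen. Of 548 alternative fits of the 24 genes with the largest changes, 484 kept the call, 64 lost it and 0 turned; of 1953 fits of the other named genes, 1609 were the same, 328 lost the call, 13 gained it and 3 turned. Turned were Ltb, at 0.0085 after quantile normalization, and Atf3, at -0.0082 both with the slide range as a block and within the shared range; neither had passed. Array weights gave 1930 changed, 789 higher and 1141 lower, 1118 by at least 1.5-fold. Genes with a single probe gave 704 changed, 300 higher and 404 lower, from fewer genes tested. The slide range as a block gave 330 changed (170 higher, 160 lower, 315 by at least 1.5-fold), and the shared range alone, with fewer arrays, 175 (107 higher, 68 lower, 174 by at least 1.5-fold). The replicate number as a block gave 743 changed, 382 lower and 361 higher. Deviations of same-numbered mice had correlations of 0.167, 0.198, -0.0213 and -0.0096. Control 2 and curcumin 2 correlated best with each other, while control 1 correlated best with curcumin 4 (0.213), so not every array correlated best with its own number. These few values neither show nor exclude that the numbers pair the mice. Leaving out 1 array at a time gave 512 to 1398 changed, 237 to 547 higher, 258 to 851 lower, 426 to 977 by at least 1.5-fold, 14 to 15 lists up, 8 to 9 lists down, and 3 to 4 arrays that met the rule for the direction. The counts moved most without control 1 (701), control 4 (534), curcumin 1 (564) and curcumin 4 (512), and those lower also without curcumin 3 (398). In these fits Cstdc6 lost its call without control 1 or 4 or any 1 curcumin array, Stfa3 likewise, S100a9 and Ido1 without any 1 control array or curcumin 4, Cxcl11 without control 1, 2 or 4 or curcumin 1 or 4, Wfdc21 without control 4 or curcumin 1, 3 or 4, and Il1b without control 4 or curcumin 4. Of 89 named genes that passed, 44 kept the call in all leave-one-out fits and 26 in every fit. With an estimated correlation 2 lists passed up and 0 down, and from liver and kidney alone 8 arrays met the rule for the direction. The other settings left all counts within 1.5 times, among them quantile normalization (1108) and the shared value set to missing (1119, with 14 lists up and 8 down); list tests were not run for each probe on its own (1478 changed). Genes with a single probe also ended the list calls of cholesterol synthesis, clock, neuron and glia, smooth muscle and stress response genes, the slide block that of clock genes (adjusted p = 0.0774), and array weights and the shared value set to missing that of stress response genes (adjusted p = 0.214 and adjusted p = 0.0647). The cause was not tested. Signal over background was not used here, so its limits are not given.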

Other observations

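The gene families, the pan-epithelial list and the tests of epithelial share, of other cell types, of the slide range and of the shared value were chosen after the data were seen; the splits were planned. Among families formed by shared name stems, none of the shifts passed with an estimated correlation (lowest adjusted p = 0.132). Chemokines were lower with curcumin: of 28 tested, 10 fell and none rose (adjusted p = 5.99e-07 in camera), Cxcl9, Cxcl11 and Cxcl1 among them. Of 15 guanylate-binding and immunity-related GTPases 4 fell and none rose (adjusted p = 7.02e-09 in camera), namely Gbp3, Gbp4, Gbp8 and Iigp1. Of 52 genes with complement stems 9 fell and none rose (adjusted p = 0.000152 in camera), with C1ra at -1.56 and C4b at -1.20; this stem also took in C730049O14Rik, which is no complement gene. Of 29 C-type lectins and CD300 receptors 9 fell and 1, Clec2h, rose (adjusted p = 0.00126 in camera), with Clec10a at -1.29 and Cd300c2 at -1.20, and of 12 paired and leukocyte immunoglobulin-like receptors 3 fell and none rose (adjusted p = 0.0136 in camera), namely Pirb at -1.89, Pira1 and Sirpa. Of 39 collagens 7 fell and none rose (adjusted p = 8.71e-05 in camera), with Col18a1 at -1.39. Of 24 immunoglobulin gene segments none passed, although the family shifted down (adjusted p = 1.92e-05 in camera; adjusted p = 0.394 with an estimated correlation).

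Upward, 3 of 9 gasdermins rose and none fell (adjusted p = 0.0136 in camera): Gsdmc2, Gsdmc at 1.70 and Gsdmc3 at 1.53. Of 12 carboxylesterases 2 rose, Ces2b at 1.66 and Ces2g at 0.72 (adjusted p = 0.00637 in camera), and of 26 sulfotransferases and glucuronosyltransferases 7 rose and none fell (adjusted p = 0.00126 in camera). Of 309 solute carriers 21 rose and 8 fell, and of 72 cytochromes P450 15 rose and 2, Cyp7b1 and Cyp3a16, fell, neither family shifting as a whole (adjusted p = 0.928 and adjusted p = 0.325 in camera). Of 755 olfactory receptors 2 fell, Olfr812 and Olfr1218. Some features had a value on all 4 arrays of 1 group and on none of the other: 54 for control and 5 for curcumin, where 5033 to 8351 features lacked a value on the control arrays and 6911 to 10529 on the curcumin arrays. The 5 for curcumin included features of Tfg, Tmem245, Pde11a and Fancg. Those for control with the highest mean log ratios, picked after their values were seen, were features of Mmp8 (1.23) and Il17a (1.16). Mmp8 is in the neutrophil list and Il17a in the cytokine list. The other features for control had mean log ratios from -0.27 to 0.50.

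The rise of colonocyte and xenobiotic genes and the fall of myeloid genes were weighed together, with genes at the shared value left out of both sides of each comparison of cell types. The 25 colonocyte genes had a median log2 fold change 0.40 (95% interval 0.166 to 0.664) above that of 20 pan-epithelial genes, which was 0.35. The difference per array had an exact permutation p of 0.0286, two-sided, the smallest that 8 arrays can give. This p was not adjusted for the same test in phase I (exact permutation p = 0.229) and phase II (exact permutation p = 0.286). For the colonocyte genes these values argue against a larger share of epithelium as the whole cause, but do not exclude it. For xenobiotic genes that explanation stays open, as their medians differed from the pan-epithelial median by 0.048 (-0.332 to 0.341) in phase I and by -0.048 (-0.22 to 0.0871) in phase II. An earlier comparison with only the genes that had passed was set aside, because that selection raises their median. More of every other cell type alike in the control pieces is not borne out, since smooth muscle genes had a median of 0.13 (0.07 to 0.22), neuron and glia genes 0.10 (0.03 to 0.28) and endothelial genes -0.23 (-0.39 to -0.11), the last of which went the way of macrophage genes, at -0.98 (-1.13 to -0.77), but by less. The slide range was weighed over 161 members of the colonocyte, phase I, phase II, macrophage and neutrophil lists. Their median change within the shared range was 0.999 times (0.842 to 1.14) the full one. The slide range is not borne out by this, but the shared range holds only curcumin arrays 1 and 2. This interval, like the other 95% intervals of the section, resamples genes and not mice, so it leaves out the spread between mice. The shared value is not borne out either, since 2.11% of all changed genes and features held it on any array. Diet, injury score and a shift in cell composition could each give what remains, and because the arrayed mice were chosen by injury score these data cannot separate them. A reference that differed between the diets, which the channel labels leave possible, could also add to every difference, and this was not tested.

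Adipocyte genes had a median log2 fold change of 0.73 (0.325 to 1.18) over the 14 that held the shared value on no array. A larger share of epithelium as the whole cause would leave genes that epithelium does not make level or lower. Which of the 14 epithelium also makes was not examined, so their median does not exclude that explanation. Whether fat tissue was left on the curcumin pieces, or the mice had more body fat, was not tested, because the genes that would show it are those of the pattern itself.

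Among the 35 splits of the 8 arrays into 4 and 4, only 1, the real one, gave as many changed genes, and likewise for higher genes, lower genes and those changed by at least 1.5-fold, the highest other split giving 9 changed. For counts in 1 direction, of genes or lists, each other split was counted by the larger of its 2 directions, since a split other than the real one has no set direction. For lists shifted towards curcumin 1 split of 35 gave as many as the real 15, the highest other giving 12. For lists shifted towards control 17 splits gave as many as the real 8 in either direction, the highest other giving 12. This sets the smaller of the real split's 2 directions against the larger of each other split. It therefore cannot decide whether chance gives that count, and chance is not excluded for it.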
